A study of Homo sapiens with 53 samples.

How the data were processed

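Gene expression was measured by bulk RNA sequencing in 48 libraries (16 groups of 3) and by droplet single-cell RNA sequencing in 5 libraries, all from H9 (WA09) cells of a triple reporter line. Per the labels, the single-cell cardiac Control received 5 uM CHIR, 5 ng/mL FGF2 and 5 uM IWR. Single-cell cVO cultures received these and 10 uM SB, VEGF, ANG1 and ANG2 at 50 ng/mL each, PDGFBB at 10 ng/mL and TGFB at 2 ng/mL. Doses are not given here for the bulk libraries. The sample labels of bulk cVO pair the vascular factors with the day of collection, while the treatment protocol starts them at day 5; the protocol was followed here. Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

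The deposited bulk table holds FPKM per gene and library, made by the authors with Trim Galore, STAR and RSEM per the submitters' processing notes. Per the labels' protocols, FastQC 0.11.2 and STAR 2.5.3a were used with GRCh38, and 85.3% of reads aligned on average. The deposited single-cell matrices hold UMI counts per gene and cell from Cell Ranger, version 3.0.0 for Control and cVO0 and 7.1.0 for cVO1 to cVO3 per the file headers. Their references list 58040 and 36601 features, of which 33961 are shared and were used here. Per the labels, 6 organoids were pooled for Control and cVO0 (about 4000 cells sought) and 9 for cVO1 to cVO3 (about 5000 sought), so the preparation, the reference and the software version changed together. The labels name 1 kit for all 5 libraries, but cVO1 to cVO3 held 5877, 7873 and 6474 barcodes, more than sought, so it is uncertain that the kit was the same. Seurat is named in the submitters' notes, but clusters made with it were not used here.

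The bulk table had 17271 features, and 16782 with at least 1 FPKM in at least 3 libraries were tested. Names for 16168 of them came from the reference gene table and for 91 from the single-cell feature lists. Another 49 small or mitochondrial RNAs were identified for an alternative scaling, since 2 unnamed features, ENSG00000265150 and ENSG00000258486, took between 0.412% and 21.2% of the FPKM total per library. No pair of libraries was identical (0 pairs), and 8 libraries correlated best with a library of another group. The first and second principal components held 40.3% and 21.8% of the variance. log2(FPKM + 1) values of all 48 libraries were fitted together in limma 3.58.1 (R 4.3.3) with trend and robust options, so that all groups share an estimate of the spread, and contrasts between groups were adjusted by Benjamini-Hochberg over genes. A call needed an adjusted p below 0.05 and a fitted change of at least 1 log2. Gene lists (33, at least 4 tested genes each) were tested in 12 contrasts with limma's camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over all 396 tests, and 141 passed; with the correlation estimated from the residuals 63 passed. Overlap between hVO-D3 and hVO-D6 was set against independent lists and against 100 simulations of unchanged groups, which yield almost no calls.

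Single cells were kept with at least 500 genes and at most 30% mitochondrial counts. Under 500 genes were 592, 94, 74, 75 and 52 barcodes of Control and cVO0 to cVO3, and over 30% mitochondrial counts 24, 2, 12, 16 and 12. Scrublet marked 9 cells in all, between 0.0127% and 0.107% per library, so it has not worked and doublets remain in the data. Control with cVO0, and cVO1 to cVO3, were clustered as 2 sets in scanpy 1.11.5 with Leiden (leidenalg 0.10.2, resolution 1, 2000 variable genes, 30 components, 15 neighbours). Clusters were named X-like from fixed markers when at least 3 markers were present in at least 25% of cells at a log2 fold of at least 1 over the other cells. A cluster stayed unnamed where another class had as many markers, where another class had more markers among its 10 leading genes by fold, or where its median UMI count was far below its library's with none of its class's markers among those 10. These naming thresholds were set after the clusters were seen, and a rule that leaves ties unnamed was added after a first clustering and moved some smooth muscle, fibroblast and epicardial clusters out of their classes. Unnamed cells made up 53.3% of Control, 51.0% of cVO0, and 44.5%, 44.4% and 39.1% of cVO1 to cVO3. UMI counts summed per library were tested in edgeR 4.0.16 (quasi-likelihood with robust option, TMM, filterByExpr, Benjamini-Hochberg), over all cells and within cardiomyocyte-like cells. The preparation, taken as 6 or 9 pooled organoids, was a term of the fit. DESeq2 1.42.0 served as an alternative. A fold against a Control sum of 0 is given as a bound from 3 UMIs over the library.

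The design, the gene lists, the cell markers, the alternatives and the rule for naming genes were chosen before the data were examined. That rule names, for each main comparison, up to 6 genes with the largest rise and 6 with the largest fall among called genes whose groups do not overlap in any replicate (chance gives 10% for 3 against 3) and whose higher group averages at least 5 FPKM or 20 CPM, leaving out features with no name and names with the prefixes of microRNAs, of small nucleolar, nuclear and ribosomal RNAs, of mitochondrial genes and of unnamed loci. RMRP and 7SK carry none of these prefixes and were kept. It adds up to 4 members per described list with the smallest adjusted p, and a fixed panel. Steps were tested on simulated data. In a simulated day 16 comparison with 16782 genes, 92% of 100 genes changed by 1.5 log2 and 92% of 100 changed by 3 log2 were recovered, with 1 false call. In simulated single-cell sums over 24367 genes, 59% and 72% were recovered, with 13 false calls. Every simulated library, the Control included, was drawn from the pooled cVO profile with the fitted spread and no preparation effect. These numbers therefore cannot show how often the real comparison of 1 Control library errs. Alternatives changed the pseudocount, the filters, the scaling, the libraries in the fit, the tool, the cell filters and the clustering, and left out each replicate in turn. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps. Coordinates come from the GRCh38 annotation.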

Results

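RNA was measured in organoids grown from H9 (WA09), an established human embryonic stem cell line carrying 3 reporters, each organoid started as a round colony 2 mm wide. The bulk data held 48 libraries in 16 groups of 3. Undifferentiated hESC were sampled at day 0. Cardiac organoids were sampled at 6 days of differentiation (day 2, day 5, day 8, day 10, day 12 and day 16) as a Control and as cVO, the cardiac vascularized organoid, which received vascular factors from day 5. Hepatic organoids were sampled at day 20 as a Control, as hVO-D3 with vascular factors from day 3 and as hVO-D6 with these factors from day 6. At day 16 single cells were sequenced in 5 libraries, 1 from the cardiac Control and 4 from cVO (cVO0 to cVO3). In the bulk table between 13139 and 15000 genes per library reached 1 FPKM (fragments per kilobase of transcript, scaled to the library), and correlations within groups lay between 0.974 and 0.994. Total counts behind each bulk library were not analysed here, so no counting interval is given for bulk values. A gene rose or fell where limma's adjusted p was below 0.05 and its fitted log2 change was at least 1 in size. Fitted changes are on log2(FPKM + 1), which understates genes of low level. FPKM are given as mean ± SD with n = 3. PECAM1 and PTPRC were not analysed here in the bulk data.

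By day 16 the cardiac Control had lost the stem cell program and held genes of heart muscle, connective tissue and liver together. POU5F1 and LIN28A, which maintain pluripotency, and DNMT3B, a DNA methyltransferase of early embryonic cells, fell. MYH6, the atrial myosin heavy chain, and MYL7, an atrial myosin light chain, rose, as did COL3A1, a fibrillar collagen. AFP and APOA2, secreted by fetal liver and yolk sac, stood among the steepest risers, and the replication helicase gene MCM5 fell.

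This comparison of Control day 16 with hESC asked what the baseline cardiac protocol yields without vascular factors. Of 16782 genes tested, 3237 rose and 2989 fell (limma with Benjamini-Hochberg adjustment). POU5F1 fell by 10.24 log2 (SE 0.25, limma adjusted p = 3.15e-30), from 1612 ± 100 to 0.343 ± 0.176 FPKM. All 12 pluripotency genes tested fell, with a median change of -7.04 (limma's camera test, adjusted p = 3.45e-11), LIN28A by -7.66, DNMT3B by -7.54, TDGF1 by -7.88 and L1TD1 by -7.36. ESRG, a noncoding RNA of stem cells, was listed at 0 in the Control against 306 ± 19 FPKM in hESC, and MT1G and ZSCAN10 changed by -8.13 and -8.11. COL3A1 reached 3948 ± 107 FPKM against 0.0233 in hESC, an increase of 11.91 log2 (SE 0.11). APOA2 rose by 10.98, AFP by 10.41 (SE 0.43, to 5505 ± 703 FPKM), IGF2 by 10.20 and APOC3 by 10.03, while DCN, a matrix proteoglycan, reached 1368 ± 214 FPKM and was listed at 0 in hESC. AFP lies on chromosome 4 at 73431138 to 73456174 (GRCh38).

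Among heart muscle genes 27 of 32 rose, none fell and the other 5 did neither (median 3.96, camera adjusted p = 1.01e-10). That list's call was lost at adjusted p = 0.168 with an estimated correlation. MYH6 rose by 8.20 (SE 0.24), MYL7 by 6.82, HSPB7 by 6.65 and MYBPC3 by 5.15. Of 20 hepatocyte genes 18 rose and none fell (median 7.44, camera adjusted p = 2.94e-08, but adjusted p = 0.271 with an estimated correlation), with AHSG up by 9.31, SERPINA1 by 9.15 and AMBP by 6.44. Fibroblast genes, 11 up and 1 down of 12, had a median of 5.47 (camera adjusted p = 5.34e-08), led by LUM at 9.95 and with POSTN at 6.28. Cell-cycle genes, 18 down and none up of 22, had a median of -2.04 (camera adjusted p = 9.78e-10, but adjusted p = 0.0624 with an estimated correlation). MCM5 fell by 3.66, as did CDC20 (-3.47), PLK1 (-3.02) and MCM3 (-2.51). For every gene list in the bulk comparisons, counts adjusted over the list alone equalled those adjusted over all genes.

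At days 2 and 5 the cVO and Control organoids expressed nearly the same genes. Both were leaving pluripotency at day 2 and passed through a primitive streak-like state, with TBXT, the mesoderm factor brachyury, and MESP1, which specifies cardiac mesoderm, expressed in each. CDH5, the endothelial adhesion protein VE-cadherin, was near its floor at day 2 and equally present in both at day 5.

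According to the protocols the factors started at day 5, so day 2 compares organoids treated alike and day 5 those at the start of treatment. At day 2 limma called 1 gene higher and 1 lower (1391 genes at an unadjusted p below 0.05), and at day 5 it called 0 (836 genes at an unadjusted p below 0.05, 3 at an adjusted p below 0.05). The gene called higher at day 2 was BOLA2, a cytosolic iron chaperone, up by 1.12 (SE 0.19, adjusted p = 0.00708). A near-identical copy of BOLA2 exists, so this call is uncertain. Below the fold limit at day 5 were COG7 at -0.66, HAMP at -0.88 and an unnamed gene, ENSG00000180672, at -0.73. These genes were named after their values were seen. TBXT at day 2 stood at 93.6 ± 22.2 FPKM in cVO and 99.5 ± 20.3 in Control, MESP1 at 15.4 and 13.8, and POU5F1 at 364 ± 18 and 427 ± 139. At day 5 CDH5 stood at 22.3 ± 1.46 FPKM in cVO and 21.4 ± 1.54 in Control. As a list, heart muscle genes lay lower in cVO at day 5 with none called (median -0.46, camera adjusted p = 2.27e-15, but adjusted p = 0.0767 with an estimated correlation), with MYH6 at 346 ± 224 against 591 ± 154 FPKM (-0.92, limma adjusted p = 0.399). Leaving out 1 library raised the calls to as many as 11 at day 2 and 12 at day 5.

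From day 8 to day 12 endothelial and endocardial genes rose in cVO against Control of the same day. Some basement membrane genes rose, and from day 10 heart muscle genes fell, but with an estimated correlation only the day 12 call of the basement membrane list was kept and neither call of the heart muscle list. TAGLN, an actin-binding protein of smooth muscle, and genes induced by TGF-beta and activin were among the earliest to rise. PDGFRB, the receptor of pericytes and other mural cells, and COL1A1, the main fibrillar collagen, rose after them. CDH5 was still near its Control level at day 8 and rose at day 10, and MYH6 and TNNT2, which encodes cardiac troponin T, fell from day 10. In both groups CDH5 had dropped between day 5 and day 8. By day 12 it was back near its day 5 level in cVO but not in Control.

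The number of genes that differed grew with time. At day 8, 239 rose and 116 fell, at day 10, 569 and 422, and at day 12, 639 and 819 (limma with Benjamini-Hochberg adjustment). Over days 8, 10, 12 and 16 together, 138 genes rose and 70 fell at every day. Of the endothelial list 7, 19 and 22 of 28 genes rose at days 8, 10 and 12 and none fell, with medians of 0.54, 1.25 and 1.43 (camera adjusted p = 3.08e-13, 6.90e-21 and 8.05e-22). CDH5 measured 6.73 ± 0.452 FPKM in cVO and 5.31 ± 0.143 in Control at day 8 (0.29, limma adjusted p = 0.202), then 12.9 ± 0.48 against 3.59 ± 0.703 at day 10 (1.61, limma adjusted p = 2.05e-11) and 22.7 ± 2.28 against 5.04 ± 0.904 at day 12 (1.98, limma adjusted p = 5.27e-14). CDH5 lies on chromosome 16 at 66366690 to 66404784 (GRCh38). Of 7 endocardial genes 3, 4 and 4 rose (camera adjusted p = 3.84e-04, 1.18e-04 and 7.54e-04). Of 10 basement membrane genes 2, 4 and 4 rose (camera adjusted p = 1.70e-04, 1.31e-05 and 9.00e-07), with the day 8 and day 10 calls lost at adjusted p = 0.123 and 0.0698 with an estimated correlation. Of 10 TGF-beta and activin targets 4 rose at day 8 (median 0.29, camera adjusted p = 1.71e-07). TAGLN rose by 1.43 at day 8 (limma adjusted p = 9.95e-07), to 451 ± 16.3 FPKM against 167 ± 2.15. The rise did not last, with TAGLN at 0.79 at day 10, 0.07 at day 12 (limma adjusted p = 0.810) and -0.96 at day 16.

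Of 32 heart muscle genes 2 rose and 1 fell at day 8, 2 rose and 12 fell at day 10, and 2 rose and 21 fell at day 12. Their medians were -0.32, -0.82 and -1.37, with a camera adjusted p of 0.563, 0.00112 and 5.22e-06; the day 10 and day 12 calls were lost at adjusted p = 0.559 and 0.343 with an estimated correlation. MYH6 stood at -0.75 at day 8, below the fold limit, then fell by 1.09 at day 10 and by 1.94 at day 12, where it measured 122 ± 9.35 FPKM against 474 ± 93.2. TNNT2 fell by 1.02 at day 10 and by 1.56 at day 12, when NKX2-5, a cardiac transcription factor, fell by 1.38. PDGFRB rose by 1.18 at day 10 and by 1.89 at day 12. COL1A1 stood at 0.86 at day 10 and rose by 1.22 at day 12, to 1442 ± 89.3 FPKM against 618 ± 45.2. ALB, the plasma protein albumin, rose by 2.08 at day 10 and by 1.80 at day 12, from low levels of 7.48 and 12.3 FPKM in Control.

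**Figure D1:**
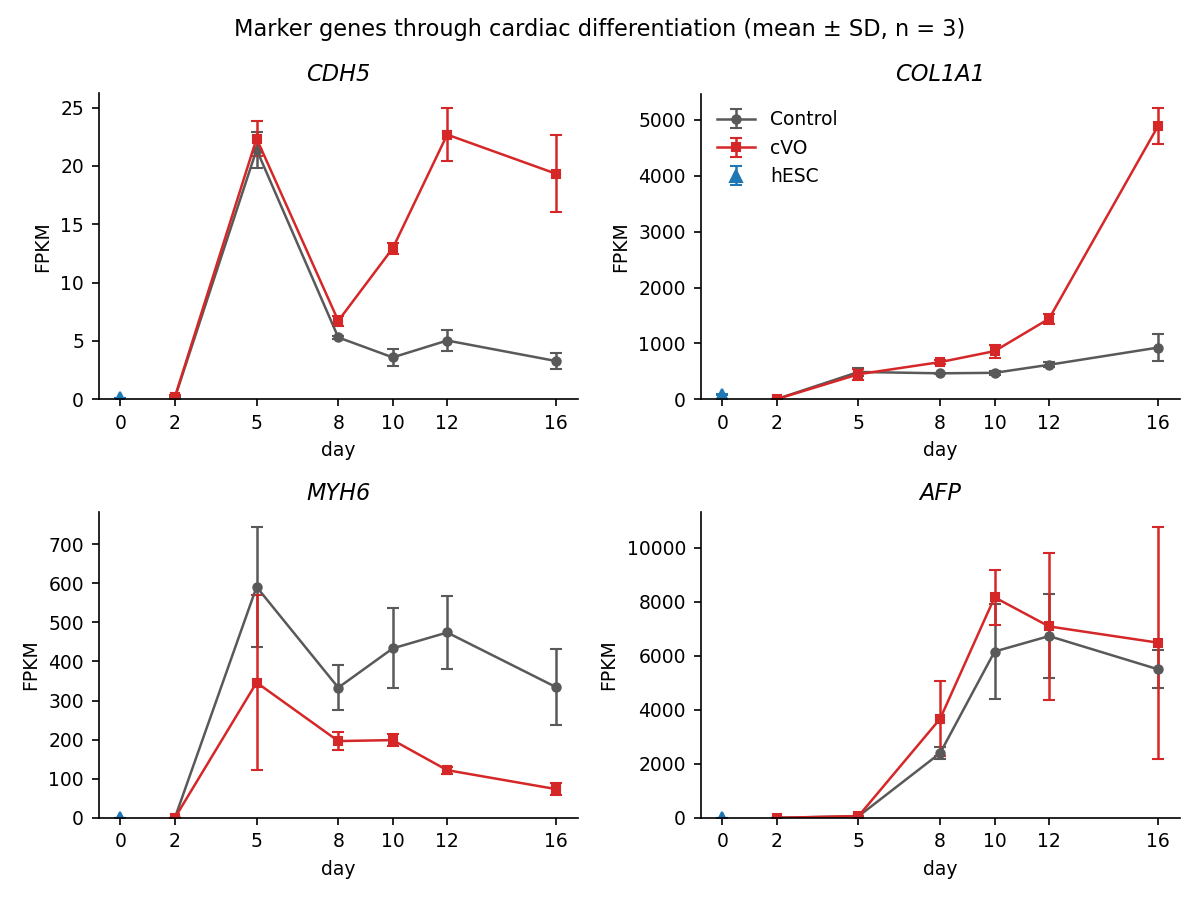
FPKM of CDH5, COL1A1, MYH6 and AFP by day of differentiation in hESC, cardiac Control and cVO, as means with SD bars (n = 3 libraries). After day 8 CDH5 and COL1A1 lie above Control and MYH6 below, and AFP does not separate at day 16. CDH5 is about as high in both groups at day 5 as in cVO at day 12.

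**Figure D2:**
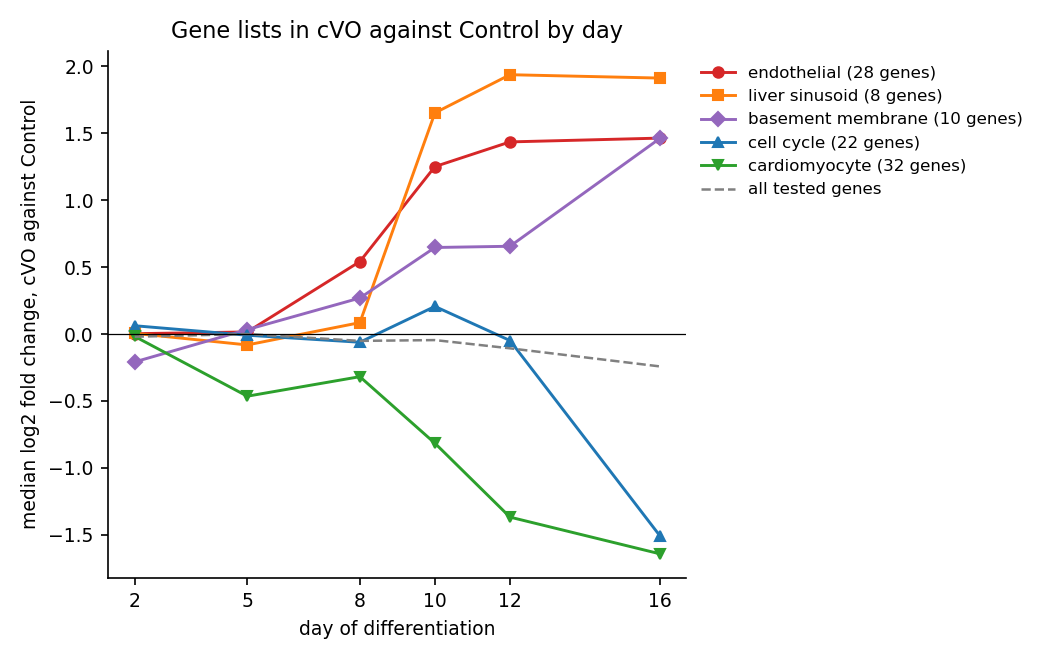
Median log2 change in cVO against Control of the endothelial, liver sinusoid, basement membrane, cell-cycle and heart muscle lists and of all genes tested, by day. The endothelial median goes from 0.54 at day 8 to 1.46 at day 16 and the heart muscle median from -0.32 to -1.64, while the median of all genes falls to -0.24.

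At day 16 cVO carried more endothelial, endocardial, liver sinusoid-type and basement membrane transcripts than the cardiac Control. CDH5 and ENG, the endothelial co-receptor endoglin, rose, with NPR3, the natriuretic peptide receptor of endocardium, and OIT3, a gene of liver sinusoidal endothelium. COL4A1 and NID1, which build the vascular basement membrane, and ANGPT2, a ligand that loosens vessel walls, rose too. COLEC11, a collectin secreted by liver and stellate cells, was among the steepest risers.

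The day 16 comparison asked what the vascular factors changed by the end of the cardiac protocol. In it 774 genes rose and 1387 fell (limma with Benjamini-Hochberg adjustment). COLEC11 rose by 6.10 (SE 0.18, limma adjusted p = 1.29e-25), to 367 ± 28.8 FPKM against 4.48 ± 1.38; it lies on chromosome 2 at 3594832 to 3644644 (GRCh38). PLA2G5, a secreted phospholipase, rose by 5.47, HTRA3, a serine protease, by 5.39, SAA1, an acute-phase protein, by 4.94, and TOX2 by 4.64. Of 28 endothelial genes 18 rose and none fell (median 1.46, camera adjusted p = 7.26e-18). CDH5 rose by 2.25 (limma adjusted p = 8.13e-16), to 19.3 ± 3.31 FPKM against 3.28 ± 0.682, ENG by 2.57, CLEC14A by 2.30 and CD34 by 1.68. Of 7 endocardial genes 3 rose and none fell (median 0.80, camera adjusted p = 0.00115), NPR3 by 3.94, ADGRG6 by 2.57 and TMEM100 by 2.49. Of 8 liver sinusoid genes 5 rose and 1 fell (median 1.91, camera adjusted p = 1.22e-05). OIT3 rose by 4.04 (SE 0.12), to 47.2 ± 3.77 FPKM, FCN3 by 2.85, CLEC1B by 2.74 and STAB1 by 2.13, while STAB2, a scavenger receptor of the same cells, changed by -1.37. OIT3 lies on chromosome 10 at 72893584 to 72933036 (GRCh38).

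Of 10 basement membrane genes 6 rose and none fell (median 1.46, camera adjusted p = 1.32e-08). COL4A1 (chromosome 13, 110148963 to 110307157, GRCh38) rose by 2.67 (SE 0.13, limma adjusted p = 3.21e-19), to 654 ± 21.7 FPKM against 102 ± 9.35, NID1 by 3.47, NID2 by 2.62 and COL4A2 by 2.58. Of 8 pericyte genes 4 rose and 1 fell (median 0.70, camera adjusted p = 0.00935); PDGFRB rose by 1.43, NOTCH3 by 1.32 and CSPG4 by 1.04, but RGS5, a G-protein regulator of mural cells, fell by 2.32. Of 10 angiogenic ligands 2 rose, ANGPT2 by 2.41 and PDGFA by 1.74 (median 0.38, camera adjusted p = 2.14e-04). Of 12 fibroblast genes 5 rose and 2 fell (median 0.63, camera adjusted p = 0.00633, but adjusted p = 0.197 with an estimated correlation). COL1A1 rose by 2.43 (limma adjusted p = 1.61e-14), to 4887 ± 324 FPKM against 926 ± 243, LOX by 2.10 and FN1 by 2.08, while OGN fell by 1.63.

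Heart muscle and cell division genes were lower in cVO at day 16, though the call of the heart muscle list was lost with an estimated correlation (adjusted p = 0.429). MYH7, the ventricular myosin heavy chain, MYH6 and TNNT2 fell, as did CCNB1, the mitotic cyclin, and PCNA, the replication clamp. MGP, which inhibits calcification of vessel walls, and SLC2A1, the glucose transporter induced in low oxygen, fell as well. Hepatocyte genes split, with TF, the iron carrier transferrin, up and the fibrinogen gene FGG down.

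MGP fell by 5.44 (SE 0.26, limma adjusted p = 4.46e-20), to 2.94 ± 1.53 FPKM from 161 ± 22.2 in Control; it lies on chromosome 12 at 14880864 to 14885857 (GRCh38). SFRP2 fell by 4.03, as did PRSS35 (-4.02), RSPO2 (-3.86), UGT2B11 (-3.80) and RELN (-3.74). Of 32 heart muscle genes 21 fell and 1 rose (median -1.64, camera adjusted p = 8.18e-05, but adjusted p = 0.429 with an estimated correlation). MYH7 (chromosome 14, 23412740 to 23435660, GRCh38) fell by 3.32 (SE 0.31, limma adjusted p = 1.08e-11), as did MYOM1 (-2.63), NEBL (-2.07) and MYBPC3 (-2.05). MYH6 fell by 2.15, to 73.4 ± 14.7 FPKM against 334 ± 97.6, as did TNNT2 (-2.25) and NKX2-5 (-1.26). Of 22 cell-cycle genes 20 fell and none rose (median -1.51, camera adjusted p = 1.34e-13). CCNB1 (chromosome 5, 69167135 to 69178245, GRCh38) fell by 1.81 (SE 0.10, limma adjusted p = 6.62e-18), as did MCM3 and PCNA (-1.59 each) and MCM5 (-1.54). Of 20 hepatocyte genes 3 rose and 6 fell, and the test pointed up while the median was -0.22 and the mean -0.37 (camera adjusted p = 0.469). TF rose by 2.91 and TDO2 by 2.33 (in cVO0 only 0.966% of its single-cell UMIs lay in endoderm-like cells), FGG fell by 2.71, as did AMBP (-1.49), and AFP at 6491 ± 4302 against 5505 ± 703 FPKM did not differ (limma adjusted p = 0.809). The FGG and AMBP calls were lost when only the groups compared entered the fit. Of 12 smooth muscle genes 1 rose, DES by 3.00, and 4 fell, among them SYNPO2 (-2.60), CNN1 (-1.14) and MYL9 (-1.12) (median -0.64, camera adjusted p = 0.574). Of 12 hypoxia genes 1 rose and 4 fell, SLC2A1 (-2.10), PDK1 (-1.35), BNIP3 and LDHA (-1.10 each) (median -0.59, camera adjusted p = 0.624).

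Scaling moved the day 16 split. The median of all genes lay at -0.24, and 35.8% of called genes rose; with median-of-ratios scaling the median was -0.03 and 57.3% rose, 1198 up and 891 down. Relative to the median of all genes, the endothelial list stood at 1.71, the basement membrane list at 1.70, the liver sinusoid list at 2.15, the heart muscle list at -1.40 and the cell-cycle list at -1.27. At day 12 the share that rose went from 43.8% to 53.7% under that scaling. Control replicate 1 and cVO replicate 3 stood apart at day 16: AFP in cVO replicate 3 was 1530 FPKM against 8751 and 9192, and without both libraries 743 genes rose and 1338 fell. Without them 4 hepatocyte genes rose and 3 fell (median 0.29).

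The day 2 organoids, sampled before treatment, served as a baseline for the day 16 effect. With the day 2 difference subtracted, CDH5 and COL4A1 were higher and MYH6 and CCNB1 lower. In this interaction 925 genes rose and 1540 fell (limma with Benjamini-Hochberg adjustment), with a median of all genes of -0.22. Of the endothelial list 16 of 28 genes rose (median 1.66, camera adjusted p = 1.90e-15), of the basement membrane list 6 of 10 (1.69, 3.19e-09), and of the liver sinusoid list 5 of 8 with 1 fall (2.01, 1.04e-05). Of 22 cell-cycle genes 21 fell (-1.54, 1.90e-15), and of 32 heart muscle genes 19 fell and 1 rose (-1.53, 8.84e-05, but adjusted p = 0.431 with an estimated correlation). With median-of-ratios scaling the share of called genes that rose was 57.7% in place of 37.5%. Day 2 is a weak baseline for such genes, since MYH6 and CDH5 differed there by only 0.01 and 0.06. Their changes less day 2, -2.17 and 2.18, nearly repeat those of day 16 alone, -2.15 and 2.25. Differences that arose between day 2 and day 5 are not removed, such as MYH6 at -0.92 at day 5 (limma adjusted p = 0.399).

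The hepatic Control at day 20 held connective tissue, mesothelial and neural genes and little of the hepatocyte program. IGF2 and H19, an imprinted pair active in fetal tissues, and COL3A1 rose. LRRN4, BNC1 and WT1, which mark mesothelium and epicardium, rose with STMN2 and DCX, cytoskeletal proteins of neurons. AFP, which had risen steeply in the cardiac Control, did not differ from hESC.

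This comparison with hESC asked what the baseline hepatic protocol yields. It found 3526 genes higher and 2215 lower (limma with Benjamini-Hochberg adjustment). IGF2 rose by 11.47 (SE 0.17), to 4714 ± 613 FPKM, COL3A1 by 11.21, H19 by 9.52 (10319 ± 1539 FPKM against 13.1 ± 2.34), IGFBP5 by 8.72 and LUM by 7.72, and DCN stood at 246 ± 47.7 FPKM and was listed at 0 in hESC. All 12 pluripotency genes fell (median -6.62, camera adjusted p = 1.62e-12), POU5F1 (-10.31), TDGF1 (-8.51), ESRG (-8.17), LIN28A (-6.94) and DNMT3B (-6.58); beyond the list MT1G fell by 8.52, as did ZSCAN10 (-8.11) and CLDN6 (-8.01). Of 20 hepatocyte genes 4 rose and none fell (median 0.55, camera adjusted p = 0.506). RBP4 rose by 1.89 and TF by 1.39, and TDO2 at 11 ± 2.78 and FGG at 13 ± 0.443 FPKM were listed at 0 in hESC. AFP measured 5.30 ± 0.543 FPKM (0.64, limma adjusted p = 0.179), against 5505 in cardiac Control at day 16, and APOA1, the main protein of HDL, 2.51 against 1633. Of 10 epicardial genes 9 rose and none fell (median 3.08, camera adjusted p = 2.03e-05). ALDH1A2, which makes retinoic acid, rose by 5.48 and LRRN4 by 5.44 (SE 0.16), while WT1 at 57.2 ± 10.8 and BNC1 at 31.6 ± 3.68 FPKM were listed at 0 in hESC. Of 17 neural genes 14 rose and 1 fell (median 3.22, camera adjusted p = 5.22e-06), STMN2 by 6.44, DCX by 4.28, NEUROD1 by 3.22 and TFAP2B by 2.72. Of 12 fibroblast genes 10 rose and 1 fell (median 4.27, camera adjusted p = 4.72e-06), among them POSTN by 6.54 and LOX by 5.12.

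Vascular factors from day 3 raised endothelial, basement membrane and macrophage genes in the hepatic organoids and lowered mesothelial and neural ones. ESM1, a proteoglycan of sprouting endothelium, CDH5 and FLT1, a VEGF receptor, rose. C1QC, a complement subunit made by macrophages, and CSF1R, the receptor they need to survive, rose too. UPK3B and LRRN4 of mesothelium fell, and KDR, the main VEGF receptor, fell against the other endothelial genes. HAND1 and GATA4, transcription factors of early heart and lateral mesoderm, fell.

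In hVO-D3, 731 genes rose and 832 fell against the hepatic Control (limma with Benjamini-Hochberg adjustment). ESM1 (chromosome 5, 54977867 to 55022671, GRCh38) rose by 6.07 (SE 0.21, limma adjusted p = 1.72e-24), to 117 ± 8.41 FPKM against 0.823 ± 0.548. CTHRC1 rose by 5.02, CD93 by 4.93, GJA4 by 4.79, ECSCR by 4.78 and FN1 by 4.55. Of 28 endothelial genes 23 rose and 1, KDR, fell (median 2.79, camera adjusted p = 2.47e-28). CDH5 rose by 4.21 (SE 0.15, limma adjusted p = 3.92e-24), to 36.9 ± 5.5 FPKM against 1.05 ± 0.286, FLT1 by 3.86 and CD34 by 3.65, and KDR fell by 2.25, to 18.3 ± 3.66 FPKM from 90.3 ± 10.7. Of 10 basement membrane genes 6 rose and none fell (median 1.63, camera adjusted p = 1.13e-10), COL4A1 by 3.56, LAMA4 by 3.44, COL4A2 by 2.77 and NID1 by 2.10. All 4 macrophage genes rose (median 1.98, camera adjusted p = 7.29e-07), among them CSF1R by 2.09, CD163 by 1.88 and CD68 by 1.66. C1QC (chromosome 1, 22643014 to 22648110, GRCh38) rose by 4.09 (SE 0.17, limma adjusted p = 1.32e-21), to 21.6 ± 8.95 FPKM.

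PLA2G2A, a secreted phospholipase (chromosome 1, 19975431 to 19980416, GRCh38), fell by 6.34 (SE 0.31), as did SLC7A4 (-5.60), SLPI (-5.46), PARM1 (-5.39) and the complement gene C3 (-5.17). UPK3B (chromosome 7, 76510525 to 76516522, GRCh38) fell by 5.41 (SE 0.24), to 1.27 ± 0.289 FPKM from 96.8 ± 23.2. Of 10 epicardial genes 9 fell and none rose (median -2.36, camera adjusted p = 1.07e-09), LRRN4 (-4.50), BNC1 (-3.34) and MSLN (-2.53). Of 17 neural genes 8 fell and none rose (median -0.99, camera adjusted p = 4.72e-06), SOX10 (-2.30), STMN2 (-1.99), DCX (-1.55) and TFAP2B (-1.41). Of 16 cardiac progenitor genes 9 fell and 1 rose (median -1.17, camera adjusted p = 4.23e-05, but adjusted p = 0.0683 with an estimated correlation), HAND1 (-4.62), GATA4 (-2.33) and ISL1 (-2.14). Of 20 hepatocyte genes 3 fell, RBP4 (-1.77), APOA2 (-1.66) and AFP (-1.30), and none rose (median -0.21, camera adjusted p = 0.870). The APOA2 call was lost without hepatic Control replicate 3 (-1.21) and without hVO-D3 replicate 2 (-1.46), and the AFP call without hepatic Control replicate 1 (-1.23) and without hVO-D3 replicate 2 (-1.05).

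Vascular factors from day 6 raised the endothelial genes less and did not raise macrophage genes. ESM1, CDH5 and FLT1 rose and KDR fell again. GATA6 and GATA4, transcription factors of mesoderm and endoderm, fell with HAND1, and BNC1 and WT1 of mesothelium fell. C1QC and CD68, a lysosomal protein of macrophages, stayed near the hepatic Control.

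In hVO-D6, 509 genes rose and 806 fell against the hepatic Control (limma with Benjamini-Hochberg adjustment). ESM1 rose by 4.89, to 51.4 ± 4.69 FPKM, CTHRC1 by 4.42, ECSCR by 4.03, GJA4 by 4.00 and CD93 by 3.96. RMRP, a small noncoding RNA, rose by 4.02 with a wide spread of 1399 ± 1778 FPKM (SE 1.22, limma adjusted p = 0.00964), a call lost without hVO-D6 replicate 2 (2.94) or hepatic Control replicate 3 (3.31). Of 28 endothelial genes 20 rose and KDR fell (median 1.92, camera adjusted p = 1.93e-17), FLT1 rising by 3.24, CDH5 by 3.03 (SE 0.15, to 15.9 ± 3.63 FPKM) and KDR falling to 12.4 FPKM. Of 10 basement membrane genes 5 rose and none fell (median 0.57, camera adjusted p = 0.00185, but adjusted p = 0.203 with an estimated correlation), LAMA4 by 2.81, COL4A1 by 2.75, COL4A2 by 1.58 and NID1 by 1.27. C3 fell by 6.28, as did UPK3B (-5.79), PLA2G2A (-5.59), SLC7A4 (-5.49), LRRN4 (-5.37) and SLPI (-5.06). Of 10 epicardial genes 9 fell (median -2.12, camera adjusted p = 3.37e-13), BNC1 (-3.91) and WT1 (-3.72). Of 16 cardiac progenitor genes 10 fell and 1 rose (median -1.59, camera adjusted p = 4.54e-12), HAND1 (-4.89) and GATA6 (-4.84) among them. None of 4 macrophage genes was called, with CD68 at 0.43 (limma adjusted p = 0.107) and CD163 at 0.01, and C1QC stood at -0.30 (limma adjusted p = 0.174). Of 20 hepatocyte genes 4 fell and none rose (camera adjusted p = 0.137), FGG (-3.79), AFP (-2.17), RBP4 (-1.99) and APOA2 (-1.83), the last lost without hepatic Control replicate 3 (-1.38). With library totals rescaled to equal sums (TPM) the share of called genes that rose was 24.3% in place of 38.7%, and the median of all genes -0.18 in place of 0.01.

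**Figure D3:**
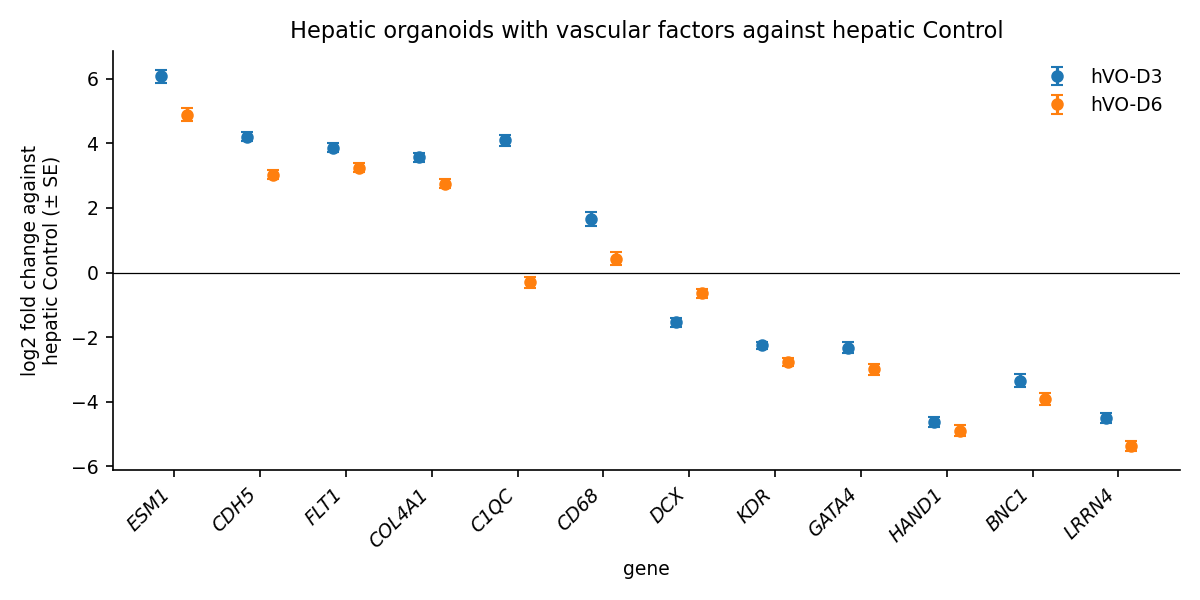
Fitted log2 change with SE of 12 genes in hVO-D3 and hVO-D6 against the hepatic Control, n = 3 libraries per group. ESM1 (6.07 and 4.89) and CDH5 (4.21 and 3.03) rise under both schedules, C1QC rises by 4.09 in hVO-D3 and stands at -0.30 in hVO-D6, and KDR, HAND1, BNC1 and LRRN4 fall under both.

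The schedules had many called genes in common, and macrophage, endothelial and fibroblast genes were among those that differed. C1QC and TYROBP, an adaptor of myeloid receptors, CDH5, and COL1A1 were lower when the factors came at day 6. MYH3, the embryonic myosin, was called higher there but varied widely between replicates.

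Of the genes called in hVO-D3 and in hVO-D6 against the same Control, 388 rose in both, where independent lists give 22.2. Another 552 fell in both, against 40.0. Simulated unchanged groups gave 0 in each direction, but such groups yield almost no calls. That 0 is therefore no reference for long lists of called genes that share a Control. The 3 shared Control libraries cannot be divided into parts of at least 2, and part of the excess may come from them. Compared directly, hVO-D6 had 103 genes higher and 232 lower than hVO-D3 (limma with Benjamini-Hochberg adjustment); without hVO-D6 replicate 3 the total was 553. Rescaling library totals to equal sums (TPM) moved the share that rose from 30.7% to 11.8% and the median of all genes from 0.07 to -0.08. C1QC fell by 4.39 (SE 0.17, limma adjusted p = 3.43e-21), as did PRG2 (-3.17), TYROBP (-2.72), GATA6 (-2.60) and MMP9 (-2.29), and CLC, an eosinophil protein, was listed at 0 against 9.66 ± 8.14 FPKM. All 4 macrophage genes fell (median -1.95, camera adjusted p = 1.35e-11), among them CSF1R (-2.03), CD163 (-1.87) and CD68 (-1.22). Of 28 endothelial genes 8 fell and none rose (median -0.70, camera adjusted p = 9.53e-17), CLEC14A (-2.17), CD34 (-1.19) and CDH5 (-1.18), with SOX7 (-1.13). Of 12 fibroblast genes 6 fell and none rose (mean -0.86, camera adjusted p = 1.35e-11), COL1A1 (-1.56), FN1 (-1.32), COL3A1 (-1.23) and LOX (-1.18). RMRP rose by 6.30, the small RNA 7SK by 4.00, MYL11 by 2.94, MYL1 by 2.69, MYH3 by 2.61 and TNNC2 by 2.40, all with an SD above the mean in hVO-D6, as in MYL11 at 42.6 ± 49.7 FPKM. Of 32 heart muscle genes 7 rose, ACTC1 by 2.22, TNNT2 by 2.04, TNNC1 by 1.54 and TNNI1 by 1.47, and none fell (median 0.29, camera adjusted p = 0.126). In the same list MYH6 at -0.06 and MYH7 at 0.20 were not called (limma adjusted p = 0.874 and 0.675). The calls of RMRP, 7SK, MMP9 and the 8 muscle genes named as higher were lost when only the groups compared entered the fit. The 7SK call was also lost without hVO-D6 replicate 2 (2.86).

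The single-cell libraries of day 16 asked which cells the cardiac organoids held. Endothelial-like, cardiomyocyte-like, epicardial-like and endoderm-like cells were found in every library. The Control and cVO0, both from 6 pooled organoids, had like shares of endothelial-like cells, and cVO0 more cardiomyocyte-like cells. Many Control cells held few UMIs, and they count in the denominator of its shares. Clusters passed the limit for the name pericyte-like in cVO1 to cVO3 alone, while in cVO0 clusters with fewer pericyte markers stayed unnamed.

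Together the 5 libraries held 26479 barcodes, of which 25560 were kept: 1913 in Control, 3638 in cVO0, and 5798, 7793 and 6418 in cVO1 to cVO3. Total counts were 18122507, 26355990, 79425140, 81913370 and 96579432 UMIs (unique molecular identifiers), and median UMIs per kept cell ran from 5163 in Control to 12294.5 in cVO3. Shares above 0 carry exact binomial 95% intervals, which cover counting error only. Endothelial-like cells made up 8.00% of Control (6.82 to 9.31), 8.44% of cVO0 (7.56 to 9.39) and 14.7 ± 0.458% of cVO1 to cVO3 (SD, n = 3). Cardiomyocyte-like cells made up 2.20% of Control (1.59 to 2.96), 12.6% of cVO0 (11.6 to 13.7) and 8.78 ± 1.14% of cVO1 to cVO3. The cVO0 share thus exceeded the Control share by 10.4 points for cardiomyocyte-like and 0.44 points for endothelial-like cells. Counting cells with at least 3 markers instead gave 2.89 and 3.17 points, and on cells thinned to 2000 UMIs that count gave 10.0 points for cardiomyocyte-like and -1.34 for endothelial-like cells. The shares themselves moved too. With at least 3 markers per cell, cardiomyocyte-like cells made up 18.2% of Control, 21.1% of cVO0 and 30.8% to 39.8% of cVO1 to cVO3. With the Scrublet calls kept and the cells clustered anew, they made up 3.50% of Control and 14.1% of cVO0. Endothelial-like cells then made up 12.4%, 12.1% and 11.8% of cVO1 to cVO3, a shift larger than the SD above. That setting held 5800, 7794 and 6419 cells, so the shift came with the new clusters and names and not with added cells. In the main clustering an endothelial-like cluster of 145, 198 and 256 cells had 5 markers. Its cells lay at a median of 2.39 times the median UMIs of their library. Whether this cluster made the shift was not tested. Endoderm-like cells made up 2.61% of Control (1.95 to 3.43) and 7.50% of cVO0 (6.67 to 8.41). Epicardial-like cells made up 5.49% of Control and 2.94% of cVO0. Smooth muscle-like cells (28.1% and 0.137%) and fibroblast-like cells (0.314% and 17.4%) lay in clusters made almost wholly of 1 of the libraries, so these shares may be the library and not a type. They also depend on the naming rules, since some clusters that matched fibroblasts best stayed unnamed. In Control 2 such clusters held 17.5% of cells, and in cVO0 2, not wholly the same ones, held 2.67%. An unnamed cluster that matched smooth muscle best held 18.6% of Control and 4 cells of cVO0. That cluster and a smooth muscle-like one with 354 Control cells were shallow, with medians of 1590.5 and 1424 UMIs per cell. In Control 1296 of 1913 cells held at least 2000 UMIs, against 3489 of 3638 in cVO0. Shallow cells thus enter the denominator of every Control share. Pericyte-like cells were 0 of 1913 in Control, which allows up to 0.157% (3 cells; exact upper limit 0.193%), 0 of 3638 in cVO0, which allows up to 0.0825% (3 cells; exact upper limit 0.101%), and 8.83%, 9.86% and 9.66% in cVO1 to cVO3. These zeros depend on the naming limit of 3 markers: 3 clusters of the Control and cVO0 set matched pericytes best with 1 or 2 markers, 1 of them tied with fibroblasts, and held 0.627% of Control and 36.5% of cVO0 (1329 cells), against 0% in cVO1 to cVO3, which were clustered apart. Shares were not tested between Control and cVO0, which had 1 library each.

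**Figure D4:**
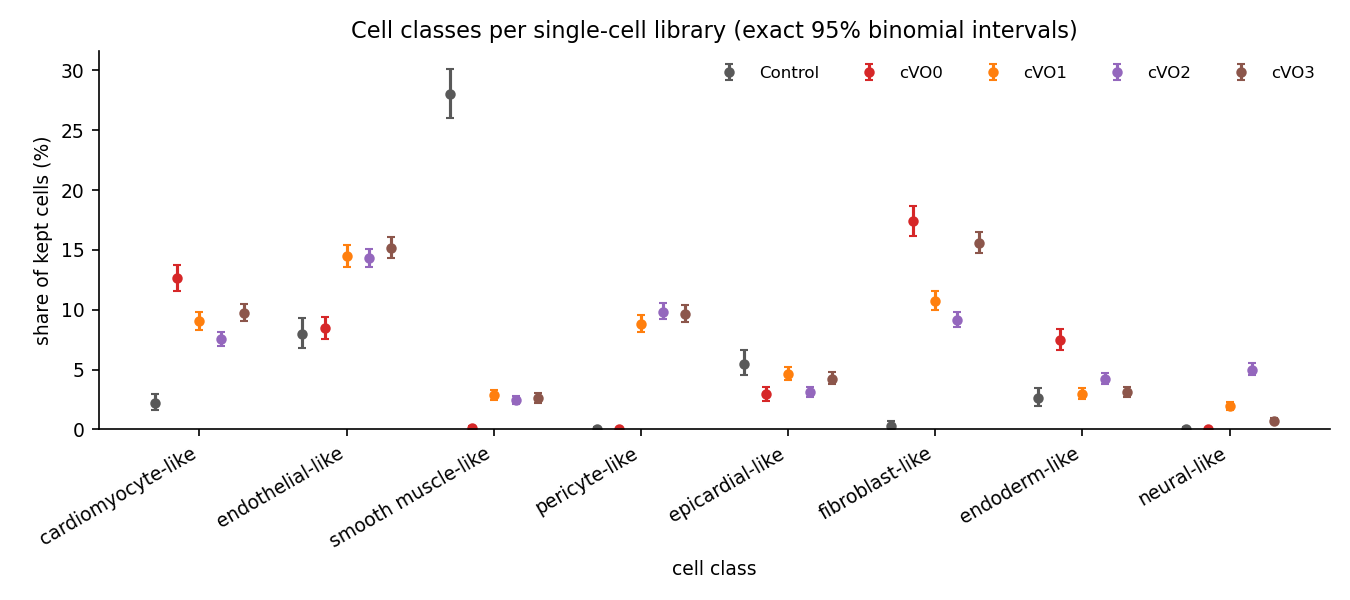
Percentage of kept cells in 8 cell classes for the Control and cVO0 to cVO3 libraries at day 16, with exact binomial 95% intervals. Endothelial-like shares are 8.00% and 8.44% in Control and cVO0, and cardiomyocyte-like shares 2.20% and 12.6%.

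Summed over cells, heart muscle, endothelial, basement membrane and hypoxia genes were higher in cVO0 than in Control, both from 6 pooled organoids. None of these list calls was kept with an estimated correlation. That form of the list test rests on the 2 residual degrees of freedom of the fit, so hardly any list could pass it. Whether the list calls hold can therefore not be decided here. Sums over cells also depend on how much of a library each class makes up. Cardiomyocyte-like cells held 247858 of 17536849 UMIs in Control and 2424554 of 26068175 in cVO0, and endothelial-like cells 988269 and 2885639. Within these classes the medians of the heart muscle and endothelial lists were 0.72 and 0.002, against 2.87 and 0.89 over all cells. NPPA, the atrial natriuretic peptide, MYH6 and PECAM1, an endothelial adhesion molecule, rose. NID1 of the basement membrane and VEGFA, the main endothelial growth factor, rose, and UPK3B of mesothelium fell. In the bulk libraries of day 16 MYH6 and PDK1 of the hypoxia list fell instead, while NPPA was not called (0.07, limma adjusted p = 0.849).

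In this test 1793 genes were higher and 1755 lower of 24367 (edgeR with Benjamini-Hochberg adjustment). Without the preparation term edgeR called 0, and DESeq2 with that term called 2939; at an unadjusted p below 0.05 edgeR had 9614. The change comes from Control against cVO0 alone and the spread from cVO1 to cVO3, with 2 residual degrees of freedom, so a lone Control is assumed to vary like those libraries. AGR2, a secretory pathway protein of epithelium, had 0 UMIs in Control and 2089 in cVO0, at least 8.87 log2 higher, but only 0.166 to 0.233 counts scaled to the library total (CPM) in cVO1 to cVO3. PLA2G5 was higher by 7.35 (SE 0.21, edgeR adjusted p = 3.04e-05; 0.342 and 43.4 CPM, and 35.8 to 36.3 in cVO1 to cVO3), and COLEC11 by 6.61 (SE 0.23, edgeR adjusted p = 7.69e-05; 4.16 and 315 CPM, but 7.05 to 8.95, near the Control). ZFPM2-AS1 and ZNF625 had 0 UMIs in Control and 21 and 5 in cVO0, at least 2.24 and 0.17 log2 higher, the latter below the fold limit. They stood at 0.806 and 0.192 CPM in cVO0 but at 96.2 to 109 and 24.9 to 29.9 in cVO1 to cVO3. Both thus reached 20 CPM only through cVO1 to cVO3, whose preparation, reference and software version differed. PPBP changed by -7.68, CCNO by -7.59, PLPPR3 by -7.44, RIPPLY3 by -4.90, UPK3B by -3.94 and SOX2 by -3.69. PLPPR3 stood at 26.1 CPM in Control and 0.115 in cVO0 but at 8.78 to 20.6 in cVO1 to cVO3, and RIPPLY3 at 20.8 and 0.537 but at 8.07 to 18.7; without the preparation term their changes were -1.73 and -1.56. The ZNF625 call was lost without cVO replicate 1, those of RIPPLY3 and SOX2 without cVO replicate 1 (-4.94 and -3.73) or 3 (-4.94 and -3.73), and those of CCNO and PLPPR3 without cVO replicate 2 (-7.62 and -7.48).

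Of 34 heart muscle genes 27 rose, or 30 adjusted over the list alone, and none fell (median 2.87, camera adjusted p = 8.06e-38). NPPA rose by 5.28, MYH6 by 3.76 (SE 0.26, edgeR adjusted p = 2.95e-04), PLN by 3.34 and NEBL by 2.22. Of 29 endothelial genes 12 rose and 1 fell, or 14 and 1 adjusted over the list alone (median 0.89, camera adjusted p = 3.21e-08), PECAM1 by 1.96, FLT1 by 1.94 and ESAM by 1.77, with SOX17 at -1.71. Of 10 basement membrane genes 5 rose under both adjustments (median 1.25, camera adjusted p = 1.04e-13), NID1 by 3.05, NID2 by 2.55, COL4A2 by 1.95 and LAMA4 by 1.94. Of 11 pericyte genes 6 rose (median 1.19, camera adjusted p = 1.12e-05), CSPG4 by 2.28, PDGFRB by 1.80, ANPEP by 1.59 and NOTCH3 by 1.16. ANPEP stood at 3.65 CPM in Control and 8.52 in cVO0 but at 0.932 to 1.25, below Control, in cVO1 to cVO3. Of 12 hypoxia genes 8 rose (median 1.25, camera adjusted p = 9.94e-12), VEGFA by 2.22, EGLN3 by 2.10, ANKRD37 by 2.05 (6.90 and 22.1 CPM, but 7.20 to 9.91 in cVO1 to cVO3) and PDK1 by 1.08. In the bulk libraries of day 16 PDK1 fell by 1.35. Of 11 immediate early and stress genes 5 rose and none fell (median 0.96, camera adjusted p = 1.09e-07). Each of these 6 list calls was lost with an estimated correlation, a test on 2 residual degrees of freedom that cannot decide whether they hold. Of 22 cell-cycle genes 1 rose, RRM2 by 1.07, and 1, CENPF, fell by 1.03 (median 0.090, camera adjusted p = 0.924), but in cVO1 to cVO3 both lay on the other side of Control, RRM2 at 26.6 to 29.4 CPM against 38.5 and CENPF at 108 to 129 against 77.0.

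Within cardiomyocyte-like cells several heart muscle transcripts were higher in cVO0 than in Control. MYL3, the ventricular myosin light chain, PLN, which restrains the calcium pump, and SMPX, a small muscle protein, rose. NPPB, a natriuretic peptide of strained muscle, rose too, but NPPB, MYL3 and SMPX were not higher in cVO1 to cVO3 than in Control. Among the falls were DKK1, a Wnt inhibitor, and INHBA, an activin subunit.

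In these cells 378 genes were higher and 111 lower of 16872 (edgeR with Benjamini-Hochberg adjustment), from 42 Control cells with 247858 UMIs and 459 cVO0 cells with 2424554. This too sets 1 Control library against 1 cVO0 library, with the spread taken from cVO1 to cVO3, and the lone Control is assumed to vary like them. The list test with an estimated correlation again rests on 2 residual degrees of freedom and cannot decide whether list calls hold. Without cVO replicate 1 the total of 489 became 306, with DESeq2 317, and without the preparation term 0; 2678 genes had an unadjusted p below 0.05. MYL3 was higher by 2.57 (SE 0.23, edgeR adjusted p = 4.41e-05; 1077 and 4737 CPM, but 901 to 1076 in cVO1 to cVO3), NPPB by 2.80 (412 and 2129 CPM, but 78.1 to 117 in cVO1 to cVO3), PLN by 2.51 (258 and 1091 CPM, and 544 to 663) and SMPX by 1.74 (448 and 1114 CPM, but 376 to 398). LAD1 changed by -5.93, DKK1 by -4.95, FST by -4.58, INHBA by -4.23 and CSAD by -3.08; of these DKK1, FST, INHBA and CSAD were not called by DESeq2. ACYP2, EGR1, H1-2, SNAPC1, DLC1 and RCOR1 had 0 UMIs in Control, so their increases are at least 2.25, 1.91, 1.63, 1.31, 1.27 and 1.10 log2, and of these ACYP2 alone was called by DESeq2. Of 32 heart muscle genes 12 rose under both adjustments and none fell (median 0.72, camera adjusted p = 9.80e-33, but adjusted p = 0.737 with an estimated correlation). Of 12 hypoxia genes 4 rose, or 5 adjusted over the list alone (median 1.01, camera adjusted p = 2.48e-11, but adjusted p = 0.737 with an estimated correlation).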

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

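Of the tests here, the exchange of columns was chosen only after the result was seen, and so were the differences between the hepatic and cardiac effects; the share of UMIs in endoderm-like cells was predicted before its result was seen.

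The cVO0 library stood far from the other 3 cVO libraries in 6 of 16 measures examined, where chance alone gives about 1 in 20. Its endothelial-like share was 8.44% against 14.3% to 15.2%, or 8.46% against 11.8% to 12.4% with the Scrublet calls kept. Its smooth muscle-like share was 0.137% against 2.44% to 2.85%, and its pericyte-like share 0% against 8.83% to 9.86%. That 0% depends on the naming limit, since clusters holding 36.5% of cVO0 matched pericytes best with fewer than 3 markers and stayed unnamed, in a set clustered apart from cVO1 to cVO3. AFP stood at 1148 CPM against 73.8 to 139, APOA1 at 1394 against 31.2 to 46.0, and CDH5 at 32.3 against 85.4 to 94.7. cVO0 was the only cVO library of its preparation, with 6 pooled organoids in place of 9 and another reference and software version, so the preparation and the culture cannot be told apart. In Control, also from 6 pooled organoids and with that reference and software version, AFP stood at 1100 CPM and APOA1 at 1325.

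The cVO effect differed between day 16 and day 2 in 2465 genes by limma's interaction contrast. The effect of the vascular factors in hVO-D3 differed from that in cVO at day 16 in 2324 genes (1380 higher, 944 lower), and the effect in hVO-D6 in 3183 genes (1979 higher, 1204 lower). The systems also differ in protocol and in day of collection.

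Hepatocyte genes were abundant in the cardiac libraries and scarce in the hepatic Control, with AFP at 5505 and 5.30 FPKM. An exchange of cardiac and hepatic columns is argued against by the heart muscle list, in which 28 of 32 genes were higher in every cardiac Control day 16 library than in every hepatic Control library and 1 was lower. Endoderm-like cells within the cardiac organoids are a candidate source: they were 2.61% of Control cells and 7.50% of cVO0 cells but held a median of 97.2% and 97.1% of the UMIs of hepatocyte genes (21 and 18 genes). In cVO1 to cVO3 the medians were 63.5%, 82.2% and 81.0%. There the class included a cluster of 551 cells led by MIR205HG, GRHL2 and WFDC2, and the cluster led by AFP and SERPINA1 held 43, 38 and 69 cells. In the Control and cVO0 set a cluster led by MIR205HG and WFDC2 had 2 endoderm markers and stayed unnamed. The medians of the 2 sets are thus not of like cells. Genes differed, from 33.3% to 100% in Control and from 0.966% (TDO2) to 100% in cVO0. The clustering used some of the same genes, the single-cell and bulk data come from different samples, and why the hepatic Control lacks these transcripts was not tested.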

How the results depend on the processing

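Tests chosen only after the result was seen were the scaling without small and mitochondrial RNAs, the fits without both day 16 libraries that stood apart, the counts on cells thinned to 2000 UMIs or with at least 2000 UMIs, the removal of the highest 5% of Scrublet scores, and all those of the endothelial-like sums.

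Of 218 counts and shares under alternatives, 186 stayed close to the value reported and 32 moved. A pseudocount of 0.1 raised the calls to 13 at day 2, 669 at day 8, 1725 at day 10, 2374 at day 12, 3528 at day 16, 2405 in hVO-D3, 2128 in hVO-D6 and 782 between hVO-D6 and hVO-D3, since it shrinks changes of low genes less. At day 2, equal library sums (TPM) and median-of-ratios scaling each gave 1 call and a fit of only the groups compared 0. TPM gave 507 calls between hVO-D6 and hVO-D3. Leaving out a replicate gave 1 to 11 calls at day 2, 0 to 12 at day 5, 253 to 553 between hVO-D6 and hVO-D3, and 306 to 666 in cardiomyocyte-like cells. No call had the opposite sign under any bulk alternative (0 genes). With an estimated correlation 63 list tests passed in place of 141.

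Without the preparation term edgeR called 0 genes over all cells, 0 in cardiomyocyte-like and 0 in endothelial-like cells, and RRM2 and ANPEP reversed to -0.13 and -0.17. DESeq2 called 317 genes in cardiomyocyte-like cells. The endothelial-like difference of 0.44 points became 3.17 with at least 3 markers per cell and -1.34 when these were counted on thinned cells, and the cardiomyocyte-like difference of 10.4 points became 2.89 with at least 3 markers, 10.0 when these were counted on thinned cells and 11.9 with each library clustered alone. Apart from the pseudocount, the cause was not tested.

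For named bulk genes, 2920 of 2942 alternative values kept their call, 22 were weaker and 0 reversed. For single-cell genes, 471 of 574 kept it, 101 were weaker and 2 reversed. Most of the weaker values came from the fit without the preparation term. No paired analysis was possible because the columns carry running sample numbers and no replicate number is shared by groups, so the planned replicate block was not run. Counting depth was lowest in the cardiomyocyte-like sums, with 42 Control cells and 247858 UMIs.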

Other observations

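Of the tests here, those of left-out libraries, of fewer cardiomyocytes and of fewer dividing cells, the divisions of libraries and the sums over endothelial-like cells were chosen only after the result was seen. Median-of-ratios scaling was chosen before the data were examined, but its use to weigh these patterns came after the result was seen.

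Heart muscle genes were lower in bulk cVO at day 16, with 21 of 32 called, though the list call was lost at adjusted p = 0.429 with an estimated correlation. Scaling between libraries is argued against as the whole cause, since 20 fell under median-of-ratios scaling (median -1.37, upper quartile -0.51). Control replicate 1 and cVO replicate 3 standing apart is argued against too, since 19 fell without both (median -1.23, upper quartile -0.48). Fewer cardiomyocytes in cVO may still account for it, but the single-cell cardiomyocyte-like share was 10.4 points higher in cVO0, with 1 Control library and other samples than the bulk, and this cannot be told apart from a change within the cells.

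Cell-cycle genes were lower as well, with 20 of 22 called. With median-of-ratios scaling 16 fell (median -1.28, upper quartile -1.01), and without both libraries 19 fell (median -1.43, upper quartile -1.19), which argues against scaling and those libraries as the whole cause. Fewer dividing cells may account for it and stay open, since in the single-cell sums the list's median was 0.090 with 1 Control library.

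The divisions of each set of 6 libraries into 3 and 3 number 10, the real one included, too few for a share below 0.05. The real division and the highest of the others called 6226 and 3 genes for Control day 16, 355 and 0 at day 8, 991 and 1 at day 10, 1458 and 1 at day 12, 2161 and 76 at day 16, 2465 and 1 for day 16 less day 2 (dividing the 6 day 16 libraries alone), 5741 and 3 for hepatic Control, 1563 and 12 for hVO-D3, 1315 and 42 for hVO-D6, and 335 and 36 between the schedules. In each of these 1 division, the real one, called as many. At day 2 the numbers were 2 and 3, with 3 divisions calling as many, and at day 5 they were 0 and 30, so another division of the day 5 libraries parted them more than the groups did; what sets those libraries apart was not tested.

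Within endothelial-like cells, a class summed after the data were seen, edgeR with Benjamini-Hochberg adjustment called 1108 genes higher and 370 lower in cVO0 of 18585, from 153 Control and 307 cVO0 cells. This sets 1 Control library against 1 cVO0 library, with the spread taken from cVO1 to cVO3. Here too the list test with an estimated correlation rests on 2 residual degrees of freedom and cannot decide whether list calls hold. DESeq2 called 1190 genes, edgeR without the preparation term 0, and leaving out a cVO1 to cVO3 library gave 1658 to 1885; at an unadjusted p below 0.05 edgeR had 4353. Of 22 cell-cycle genes 12 rose, or 17 adjusted over the list alone (median 1.90, camera adjusted p = 8.13e-17, but adjusted p = 0.787 with an estimated correlation), CCNB1 by 3.36, RRM2 by 3.51, CCNA2 by 2.81 and TOP2A by 2.24. RRM2 stood at 17.2 CPM in Control and 135 in cVO0 but at 14.5 to 19.9 in cVO1 to cVO3, and CCNB1 at 20.2 and 143 but at 15.7 to 25.9. Of 29 endothelial genes 2 rose and 6 fell, or 3 and 6 adjusted over the list alone, with SOX17 at -2.42 and CD34 at -1.76; CD34 stood at 268 CPM in Control and 54.8 in cVO0 but at 305 to 358 in cVO1 to cVO3. Among the largest falls PPBP had 358 UMIs in Control and 0 in cVO0, PF4 328 and 0, and HBD 134 and 0, which bounds their changes at -8.44, -8.32 and -7.03 log2 or lower. Over all Control cells PPBP had 361 UMIs, so nearly all lay in this class. No cluster was named haematopoietic-like and doublets remain. Whether these UMIs come from endothelial cells or from other cells clustered with them was not tested.

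In hVO-D3, 6 of 10 angiogenic ligands rose (median 1.15), 4 pericyte genes and 5 TGF-beta and activin targets, and each list passed with an estimated correlation (camera adjusted p = 0.00119, 0.00291 and 0.0205). Between hVO-D6 and hVO-D3 all 22 cell-cycle genes lay higher in hVO-D6 with 0 called (median 0.53, camera adjusted p = 0.0461 with an estimated correlation), and 4 of 17 neural genes rose. At day 12, 5 of 8 haematopoietic genes fell in cVO and the list did not pass (camera adjusted p = 0.132). At day 2, before treatment, angiogenic ligands lay lower in cVO with 0 called (median -0.24, camera adjusted p = 0.00128, and adjusted p = 0.0134 with an estimated correlation). Reporter transcripts were nearly absent from the Control and cVO0 libraries, the only 2 examined for them: GFP and CFP had 0 UMIs in Control and cVO0, and mOrange 5 in Control, in 4 cells of which 2 were endothelial-like, and 1 in cVO0, in an endothelial-like cell.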
